A study of Mus musculus with 10 samples.

How the data were processed

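The series holds 10 libraries from mouse bone marrow-derived dendritic cells, which are antigen-presenting cells grown from bone marrow progenitors with the growth factor GM-CSF. RNA sequencing was done on 6 libraries and ATAC sequencing, which maps open chromatin by transposase insertion, on 4. Groups and replicate numbers were taken from the sample titles, giving 3 vehicle (DMSO) and 3 extract (AMLE) RNA libraries and 2 and 2 ATAC libraries. The labels do not say that replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

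For RNA, the authors deposited a table of raw read counts per gene symbol, one column per library, made from stranded poly(A) libraries. The submitters' processing notes name Trim Galore 0.6.7, STAR 2.7.11b, SAMtools 1.7, FastQC, Bowtie2 2.4.4, Picard, MACS3 3.0.0a7, deepTools 3.5.1, ChIPseeker 1.30.0, HOMER and the mouse build mm10, without roles. The counting tool, its strand setting and the gene annotation are not given in the sources used here, so reads of overlapping, antisense or near-identical genes could be split or merged. For ATAC, the authors deposited 1 peak list per library with a −log10 q and a fold enrichment (a ratio over local background) for each summit, and a consensus list per group. The settings of the peak calling are not given in the sources used here. In the files the smallest −log10 q per list lay between 1.30 and 1.31, and 1543 to 2108 peaks per library had several summits; these were merged into distinct intervals. Each consensus list equalled the intersection of its 2 replicate lists. The −log10 q and fold are the authors' values for each peak and were used only to rank or filter peaks within a list.

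The count table held 24385 gene symbols, of which 6459 had no count in any library, and totals ran from 26010455 to 34208286 counts per library. No other per-sample column was left unused. Symbols of 24277 genes matched the RefSeq table of assembly GRCm38.p6, the same build as mm10, by current or older symbol. The main test was edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM factors, the default low-count filter (minimum count 10 given the group), robust dispersions and the quasi-likelihood F test, two-sided. Adjusted p-values are Benjamini-Hochberg values over the 13075 genes tested, and genes are called below 0.05. A gene counted as changed at least 2-fold when it was also at or beyond 1 on the log2 scale. Log2 fold changes are AMLE minus DMSO. Their standard errors (SE) were derived as the absolute log2 fold change over the square root of the F statistic, so they are approximate. Levels are CPM, counts scaled to the library's effective total, with the SD over 3 libraries. The test was checked on simulated counts with 200 changed genes among 13075: it recovered 59.7% of 1.5-fold, 74.6% of 2-fold and 93.9% of 4-fold changes, and 11 of its 163 calls (6.75%) were false. The simulation held far fewer changed genes than were called in the data and no pattern by replicate number. These shares therefore do not carry over to the real comparison.

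Before the data were examined, 33 gene lists were fixed, together with the designs, the alternatives and the rule for named genes. Of their 716 entries, 700 were in the count table. An older symbol matched 4 listed names, among them Clec6a, which fell on a gene already in its list and was not counted again. The mitochondrially encoded genes had no entry there, so that list gave no value. Lists with at least 5 tested genes (31) were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Members called are counted over all genes tested and, separately, adjusted over the list alone. The lists covered co-stimulation and maturation, MHC class II and class I presentation, inflammatory cytokines, anti-inflammatory and tolerogenic genes, chemokines, NF-kB, interferon-stimulated genes, pattern recognition, antigen uptake, lysosome, NRF2, aryl hydrocarbon receptor targets, endoplasmic reticulum and integrated stress, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, lipid handling, cell cycle and dendritic cell identity. Quality lists held ribosomal proteins, heat shock and p53 genes. Marker lists covered macrophages, neutrophils and granulocyte precursors, monocytes, mast cells and basophils, eosinophils, lymphocytes, plasmacytoid dendritic cells, erythroid and stromal cells. Nqo1 stood in 2 lists, the NRF2 and the aryl hydrocarbon receptor list.

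The rule named 10 fixed genes, the 6 genes with the largest rise and the 6 with the largest fall among called genes with mean CPM of at least 10 and no overlap of the groups, the 2 members with the largest absolute change per main list (called, mean CPM of at least 1), and the most abundant member of each other list. Further genes named to spell out a count of 5 or fewer, or as examples, were chosen after their values were seen. The result of 1 list member is not reported here.

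Replicate numbers recur in both groups. Deviations of same-numbered libraries from their group means correlated at 0.29, 0.28 and 0.43 for numbers 1, 2 and 3. All lay above the bound set for pairing, but such pairing was modelled only in alternative fits with a replicate block. Across the groups, libraries numbered 1 and 2 also correlated with each other (0.110 and 0.105). Those numbered 3 correlated with 1 and 2 at −0.310 to −0.266, so much of the pattern sets number 3 apart. The pairing comes from this check of the data and not from the labels. The main design, its list tests and the leave-one-out fits have no replicate block, so their p-values and SEs are unpaired. Blocked values are given where the call on a named gene or a list changed or a count of called members moved by over 1.5 times. They are also given for H2-Ab1, Ccl24, Arg1, Ctsk and Pecam1.

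ATAC peaks of the 4 libraries were merged with bedtools 2.31.1 at a minimum overlap of 1 bp into 24542 regions, and each region was described by the libraries with a called peak. Regions present in exactly 1 mixed pair of libraries, 1 from each group, gave the background. Peak numbers were compared by an exact permutation test, which with 2 against 2 cannot give a p below 0.333. The RefSeq table gives gene spans without strand, so the planned window at the transcription start became 1 kb around either annotated gene end. Of the 13075 tested genes, 13032 were placed. Gene calls were compared between region classes with two-sided Fisher's exact tests, and genes are not independent replicates. Motif content of the regions was not analysed here, since it needs a genome sequence. Leading regions are those with the highest lower −log10 q of their 2 peaks, a ranking fixed in advance; 3 per group are given.

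Alternatives were RLE size factors, library size only, DESeq2 1.42.0, limma-voom, no low-count filter, a mean CPM of at least 1, a replicate block, leaving out each library, and a test against a 1.5-fold change (glmTreat). For ATAC they were peaks with −log10 q of at least 5, an equal number of peaks per library, reciprocal overlap of 50%, the deposited consensus lists, a 3 kb window and leaving out each library. Left out together, both libraries numbered 3 formed a further alternative, as did removal of the Rn45s count and a window over the gene span with 1 kb on each side. Those 3 were chosen after seeing the data. Tables and exact tests used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots matplotlib 3.10.9.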

Results

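Dendritic cells were grown from the bone marrow of female C57BL/6 mice aged 8 to 10 weeks for 7 days with 20 ng/mL GM-CSF. Non-adherent immature cells taken on day 6 were treated for 24 h with AMLE, an extract of apple mango leaves, at 400 µg/mL, or with 0.04% DMSO as vehicle. RNA was sequenced in 3 libraries per group and open chromatin in 2 per group, the latter from 100000 cells each with transposase for 30 min at 37 °C. Total counts were 31413578, 28457863 and 28754835 in DMSO RNA replicates 1 to 3 and 26010455, 34208286 and 26325173 in the AMLE replicates. The series title names maturation and activation of the cells by the extract as its question.

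Co-stimulatory genes and the chemokine receptor gene Ccr7 rose after AMLE. Cd40, the receptor through which T cells license dendritic cells, stood at 96.4 ± 18.8 CPM (SD, n = 3) against 17.6 ± 1.71 in DMSO, a 5.47-fold rise (log2 fold change 2.45 ± 0.16, SE; edgeR adjusted p = 8.9e-05). Ccr7, the receptor that guides dendritic cells to lymph nodes, rose 2.74-fold (1.46 ± 0.10), Cd86 rose 2.73-fold (1.45 ± 0.21) and Cd80 1.71-fold (0.78 ± 0.07). In contrast, cell cycle genes fell together, with Mki67, a marker of dividing cells, at 130 ± 27.5 CPM against 535 ± 35.2 in DMSO. Of 13075 genes tested, 3004 were higher and 3346 lower in AMLE, and 722 and 575 of these changed at least 2-fold. In all 6 fits that each left out 1 library, 558 and 509 of the genes changed at least 2-fold were again called. The groups did not overlap for 7811 tested genes (59.7%), where chance gives 10%, and for 6285 of the called genes. The leading principal component held 76.6% of the variance and parted the groups, with AMLE replicate 3 (a score of 23) nearest to the DMSO libraries (−42.0 to −31.1) and AMLE replicates 1 and 2 at 38.3 and 46.5. Tested against a 1.5-fold change, 532 genes were higher and 575 lower.

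The list tests in the following paragraphs carry a common limit. At the preset correlation camera called 12 lists higher and 5 lower of 31, with an estimated correlation it called 0 (3 at unadjusted p below 0.05, all higher), and fry, which tests whether members move one way on balance and not against other genes, called 12 higher and 5 lower. The lists were not the same ones. Fry did not call NRF2 (adjusted p = 0.0740), cholesterol synthesis (0.129), ribosomal proteins (0.0653) or mast cells and basophils (0.106). It called aryl hydrocarbon receptor targets (0.000268), dendritic cell identity (0.00873) and plasmacytoid markers (0.00873) higher and endoplasmic reticulum and integrated stress (0.0029) lower, none of which camera called. With a replicate block fry also called cholesterol synthesis (0.0154) and mast cells and basophils (0.0168) higher and MHC class II (0.0341), lipid handling (0.00786) and macrophage markers (0.0203) lower, and no longer called glycolysis and hypoxia (0.0588). Camera at the preset correlation also called 8 to 18 lists in the 9 other splits of the 6 libraries. Each of those splits has both groups on each side in unequal numbers, so part of the treatment difference stays in it. Whether a list's p parts the treatment from other groupings therefore cannot be read from them. The counts of called members carry the description. They have to be read beside all tested genes, of which 22.98% were called higher and 25.59% lower. Counts near or below these shares, as in the lysosomal list (6 of 30 higher and 3 lower), do not set a list apart from other genes. Median, mean and camera direction had the same sign in every list with a camera test.

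In the co-stimulation and maturation list, 26 of 28 tested members rose and 1 fell (26 and 1 adjusted over the list alone), with a median log2 change of 1.06 (camera adjusted p = 1.6e-11; adjusted p = 0.39 with an estimated correlation). Cd200, a surface glycoprotein, rose 6.34-fold (2.67 ± 0.32) and Fscn1, the actin-bundling protein of dendrites, rose by 1.87 on the log2 scale. Cd83 (1.06) and Cd274, which encodes PD-L1 (1.10), also rose, while Icosl fell (−0.42) and Tnfsf9 was at 0.38 (adjusted p = 0.10; 0.017 with a replicate block and 0.024 without AMLE replicate 2).

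**Figure D1:**
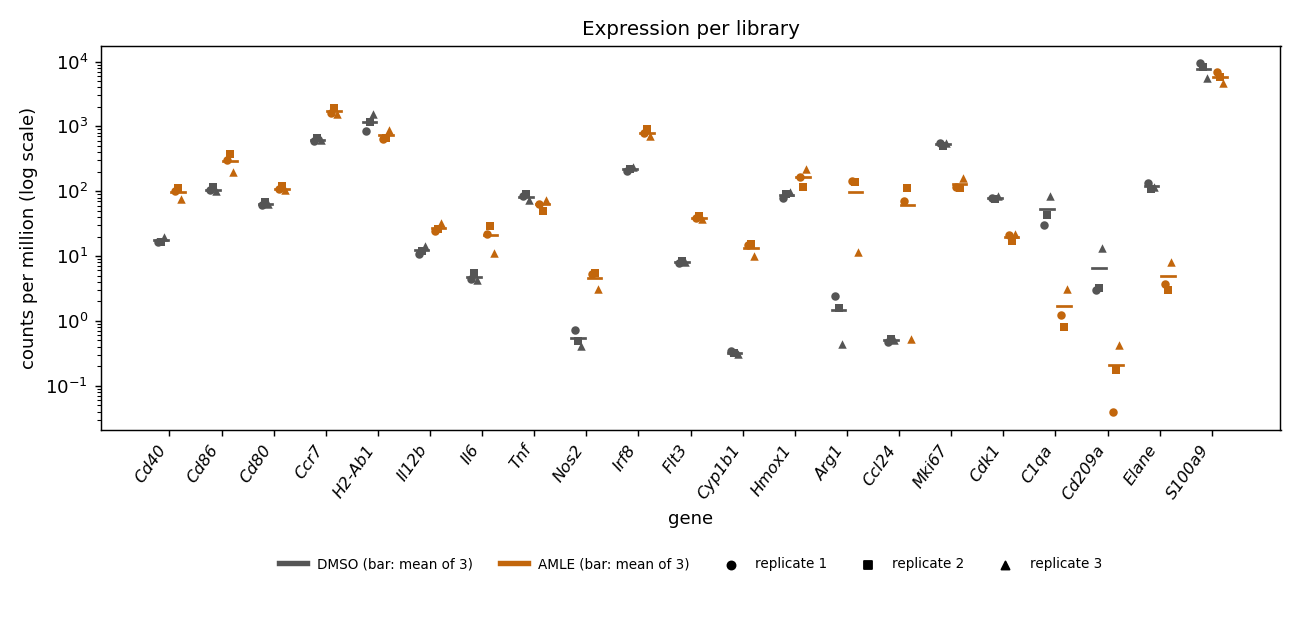
CPM of 21 genes on a log axis in each RNA library, with DMSO in grey and AMLE in orange, marker shape for the replicate and a bar at the mean of 3. Cd40 lies at 16.6 to 19.6 in DMSO and 76.0 to 113 in AMLE, and Ccl24 and Arg1 are far lower in AMLE replicate 3 than in the other AMLE libraries.

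Among 12 tested genes of MHC class II presentation, which shows peptides to CD4 T cells, 5 fell and 1 rose (5 and 1 adjusted over the list alone), with a median of −0.42 (camera adjusted p = 0.18). H2-DMb1 (−1.04 ± 0.17) and H2-DMa (−0.77 ± 0.15), which load peptide, fell, as did H2-Ob (−0.49) and H2-DMb2 (−0.40), and H2-Oa rose (0.34). H2-Ab1 fell by 0.70 on the log2 scale (SE 0.23, edgeR adjusted p = 0.041), from 1177 ± 344 to 727 ± 139 CPM with overlapping groups. Its adjusted p was 0.087, 0.10, 0.13 and 0.12 without DMSO replicate 2, DMSO replicate 3, AMLE replicate 1 and AMLE replicate 2. With a replicate block its edgeR adjusted p was 4.2e-04. H2-Ob was not called without DMSO replicate 2 (0.085), DMSO replicate 3 (0.078) or AMLE replicate 1 (0.065), so that 3 members fell in each of those fits. With a replicate block 9 members fell, 2 rose and camera called the list lower (adjusted p = 0.023), as it did without DMSO replicate 1 (0.038). Further, 2 rose without DMSO replicate 3, and 8 fell without both libraries numbered 3.

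Class I presentation genes rose in 13 of 18 tested members and fell in 3 (13 and 3 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.0022; adjusted p = 0.43 with an estimated correlation). H2-Q4 (0.84 ± 0.07) and H2-T23 (0.78 ± 0.07) rose most, and H2-K1 rose by 0.64. The members that fell, Pdia3 (−0.67), Calr (−0.60) and Canx (−0.28), are endoplasmic reticulum chaperones. H2-Q and H2-T genes have close copies, so their counts are uncertain.

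Cytokine genes rose in 10 of 16 tested members and fell in 0 (10 and 0 adjusted over the list alone), with a median of 1.07 (camera adjusted p = 0.0026; adjusted p = 0.29 with an estimated correlation). Il6 rose 4.36-fold (2.12 ± 0.34), from 4.81 to 20.9 CPM, and Il12b, a subunit of interleukins 12 and 23, rose 2.23-fold (1.16 ± 0.15). Nos2, the inducible nitric oxide synthase, rose 8.37-fold (3.07 ± 0.31) but reached only 4.61 CPM. Tnf was 82.3 ± 9.41 CPM in DMSO and 62.6 ± 12.2 in AMLE (−0.40 ± 0.15, edgeR adjusted p = 0.066; called lower with DESeq2, 0.028, and without AMLE replicate 3, 0.012). Those 2 alternatives, and the replicate block through Il18 (−0.63, adjusted p = 0.0944 in edgeR and 0.0275 with the block), gave 1 lower member. At an unadjusted p under 0.05 edgeR also gave 1, and limma-voom called 0. Il10 was not tested, with 14 counts over the 6 libraries (0, 2 and 2 in DMSO, 3, 3 and 4 in AMLE).

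Chemokines rose in 12 of 18 members and fell in 1 (14 and 1 adjusted over the list alone), with a median of 0.92 (camera adjusted p = 0.0017; adjusted p = 0.39 with an estimated correlation). Ccl5 (1.09) and Cxcl1 (1.71 ± 0.37) rose, and Cxcl10 fell (−0.72), while 2 members fell with a replicate block and without DMSO replicate 3. Ccl24, an eosinophil attractant, had the highest change of all named genes (6.91 ± 1.68, edgeR adjusted p = 0.014), at 71.5 and 111 CPM in AMLE replicates 1 and 2 but 0.535 in replicate 3, where the DMSO libraries stood at 0.477 to 0.527. Its adjusted p was 0.42 with limma-voom, 0.078 with no low-count filter, 0.054 without DMSO replicate 1 and 0.051 without DMSO replicate 2. With a replicate block its edgeR adjusted p was 0.016.

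Anti-inflammatory and tolerogenic genes rose in 13 of 23 members and fell in 2 (14 and 2 adjusted over the list alone), with a median of 0.44 and a mean of 0.83 (camera adjusted p = 0.0056; adjusted p = 0.29 with an estimated correlation). Il1rn, the interleukin 1 receptor antagonist (1.11), and Dusp1 (1.45) rose. Arg1, the arginase of alternative activation, rose by 6.03 ± 1.10 on the log2 scale. It stood at 143 and 141 CPM in AMLE replicates 1 and 2 and 11.5 in replicate 3. Its adjusted p was 0.0042 in edgeR, 0.12 with limma-voom and 2.0e-05 in edgeR with a replicate block. Havcr2, which encodes TIM-3, rose 2.91-fold (1.54 ± 0.39), from 5.48 to 15.9 CPM. That call was lost with a replicate block (0.067), with no low-count filter (0.056) and without DMSO replicate 1 (0.057), DMSO replicate 2 (0.059), AMLE replicate 1 (0.0503) or AMLE replicate 2 (0.0504). Nr4a1 (−0.42) and Tgfb1 (−0.24) fell. Nr4a1 was not called when any library other than AMLE replicate 3 was left out (0.055 to 0.12), and Tgfb1 not without DMSO replicate 2 (0.0505).

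NF-kB genes rose in 21 of 25 members and fell in 1 (24 and 1 adjusted over the list alone), with a median of 0.49 (camera adjusted p = 6.0e-08; adjusted p = 0.29 with an estimated correlation). Traf1 (1.18 ± 0.10), Rel (1.15 ± 0.08) and Nfkb2 (0.86) rose, as did the feedback inhibitors Nfkbia (0.73) and Tnfaip3 (0.67). Nfkbid fell (−0.18), a call lost when any library other than DMSO replicate 3 was left out (0.079 to 0.14). The Bcl2a1 genes in this list have near-identical copies. Interferon-stimulated genes rose in 26 of 38 members and fell in 3 (26 and 3 adjusted over the list alone), with a median of 0.55 (camera adjusted p = 1.2e-05; adjusted p = 0.39 with an estimated correlation). Irf7 (1.28), Isg15 (1.12) and Oasl1 (1.63 ± 0.13) rose, and Ifi205, a member of a family of close copies, rose by 2.89 ± 0.63. Ifi44 (−1.56), Ifit2 (−0.81) and Cmpk2 (−0.50) fell. Ifit2 was not called without DMSO replicate 3, AMLE replicate 1 or AMLE replicate 2 (0.059 to 0.066). Cmpk2 was not called without DMSO replicate 1, DMSO replicate 2, AMLE replicate 2 or AMLE replicate 3 (0.066 to 0.13).

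Genes of pattern recognition, the receptors for microbial ligands and their adaptors and kinases, moved in both directions, with 10 of 34 members lower and 5 higher (10 and 5 adjusted over the list alone; camera adjusted p = 0.62). Tlr11 (−1.68 ± 0.23) and Tlr3 (−1.60 ± 0.35) fell, and Traf6 (0.61), Ly96 (0.40), Clec7a (0.38), Irak2 (0.29) and Syk (0.28) rose. Irak2 was not called when any 1 of the DMSO libraries was left out (0.0805 to 0.11) and Ly96 not without DMSO replicate 1 (0.054), where 3 members rose. Antigen uptake receptors fell in 10 of 27 members and rose in 4 (10 and 4 adjusted over the list alone), with a median of −0.15 and a mean of −0.52 (camera adjusted p = 0.34; 0.049 without AMLE replicate 3 and 0.04 without both libraries numbered 3). Cd209a, a lectin of monocyte-derived dendritic cells, fell from 6.55 ± 5.93 to 0.211 ± 0.193 CPM (−4.94 ± 0.92), Cd163 fell (−3.90 ± 0.77) and Fcgr1 fell (−1.54). Ly75, which encodes DEC-205 (1.65), Olr1 (1.17), Tyro3 (1.00) and Clec9a (0.98) rose.

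Oxidative phosphorylation genes fell in 26 of 32 members and rose in 0 (28 and 0 adjusted over the list alone, and 0 higher at an unadjusted p under 0.05, with DESeq2 and with limma-voom), by a median of −0.31 (camera adjusted p = 1.7e-07; adjusted p = 0.43 with an estimated correlation). Atp5o (−0.67 ± 0.05) and Ndufa4 (−0.59 ± 0.09) fell most. In the glycolysis and hypoxia list 13 of 25 members rose and 1, Hk3 (−0.48), fell (13 and 1 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0011; adjusted p = 0.65 with an estimated correlation). Egln3 (1.41 ± 0.19), Bnip3 (1.15 ± 0.14), Pfkfb3 (0.96) and the glucose transporter Slc2a1 (0.40) rose, and 2 members fell without DMSO replicate 1.

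Cholesterol synthesis genes rose in 12 of 24 members and fell in 2 (13 and 2 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.013; adjusted p = 0.77 with an estimated correlation). Pmvk (0.89 ± 0.13) and Idi1 (0.84 ± 0.10) rose, and Ebp (−0.58) fell. Only 6 members rose without DMSO replicate 1 and 5 without DMSO replicate 2, 18 rose and 4 fell with a replicate block, and camera did not call the list without AMLE replicate 3 (0.085). Lipid handling genes fell in 9 of 21 members and rose in 3 (9 and 3 adjusted over the list alone; median −0.17, camera adjusted p = 0.36), with 5 lower without AMLE replicate 1 and 6 higher with a replicate block. Apoe fell (−1.47 ± 0.34), the fatty acid carriers Fabp4 (2.21 ± 0.34) and Fabp5 (1.18) rose, and so did Plin2 (0.28; 0.054 and 0.060 without DMSO replicates 1 and 2).

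Antioxidant genes of the NRF2 pathway rose in 11 of 28 members and fell in 3 (11 and 3 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 0.039; adjusted p = 0.77 with an estimated correlation). Hmox1, haem oxygenase 1, rose 1.89-fold (0.92 ± 0.21), from 88.5 ± 10.0 to 167 ± 49.6 CPM, and the cystine transporter Slc7a11 rose by 0.94 ± 0.11. G6pdx (−0.49), Tkt (−0.40) and Prdx6 (−0.23) fell, Prdx6 not without DMSO replicate 1, DMSO replicate 2 or AMLE replicate 2 (0.068 to 0.11). Camera did not call the list with a replicate block (0.055), without AMLE replicate 1 (0.082), without AMLE replicate 3 (0.11) or without both libraries numbered 3 (0.14). Among 8 aryl hydrocarbon receptor targets 5 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.44, camera adjusted p = 0.059, 0.048 without DMSO replicate 3 and 0.036 without both libraries numbered 3). Cyp1b1, a cytochrome P450, rose from 0.325 ± 0.0213 to 13.4 ± 2.84 CPM (5.35 ± 0.24), and Serpinb2 (1.51 ± 0.16), Nqo1 (0.66), Ahrr (0.49) and Tiparp (0.40) rose. When any 1 of the DMSO libraries was left out 3 of them rose, since Tiparp (0.053 to 0.13) and Ahrr (0.053 to 0.12) were not called. Slc7a5, which fell (−0.68), was not called without DMSO replicate 1, DMSO replicate 2 or AMLE replicate 1 (0.0595 to 0.0917).

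Endoplasmic reticulum and integrated stress genes fell in 13 of 28 members and rose in 9 (13 and 9 adjusted over the list alone; median −0.13, camera adjusted p = 0.34). The serine synthesis enzymes Phgdh (−2.50 ± 0.13) and Psat1 (−1.88) and the chaperone Hspa5 (−0.73) fell, and Ddit4 (1.92 ± 0.13) and Atf3 (1.29) rose. Lysosomal genes rose in 6 of 30 members and fell in 3 (5 and 3 adjusted over the list alone; median 0.004, camera adjusted p = 0.44), with Gpnmb at 1.39 ± 0.09 and Ctsk at 1.26 ± 0.36. Ctsk was not called without DMSO replicate 1 (0.087), DMSO replicate 2 (0.084) or AMLE replicate 1 (0.053). With a replicate block it was called (edgeR adjusted p = 9.0e-05). Tfeb (−0.54), Grn (−0.54) and Atp6v1h (−0.27) fell. Grn was not called when any library other than AMLE replicate 3 was left out (0.0505 to 0.090) and Atp6v1h not without AMLE replicate 1 (0.058). The count of 6 was 3 without DMSO replicate 1 or 2 and 10 with a replicate block, and 6 fell without AMLE replicate 3.

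Dendritic cell identity regulators rose in 7 of 21 members and fell in 4 (8 and 5 adjusted over the list alone; median 0.06, camera adjusted p = 0.36). Flt3, the receptor of a dendritic cell growth factor, rose 4.81-fold (2.27 ± 0.07) and Irf8 3.69-fold (1.88 ± 0.10), beside Batf3 (1.27) and Zbtb46 (0.88). Klf4 (−1.51), Cebpa (−0.47), Ikzf1 (−0.44) and Spi1 (−0.20) fell. Spi1 was not called without DMSO replicate 1, DMSO replicate 2, AMLE replicate 1 or AMLE replicate 2 (0.052 to 0.082). All 34 cell cycle genes fell (34 adjusted over the list alone), with a median of −1.96 (camera adjusted p = 3.0e-17; adjusted p = 0.39 with an estimated correlation). Cdc20 (−2.56 ± 0.19) and Plk1 (−2.49 ± 0.18), regulators of mitosis, fell most.

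**Figure D2:**
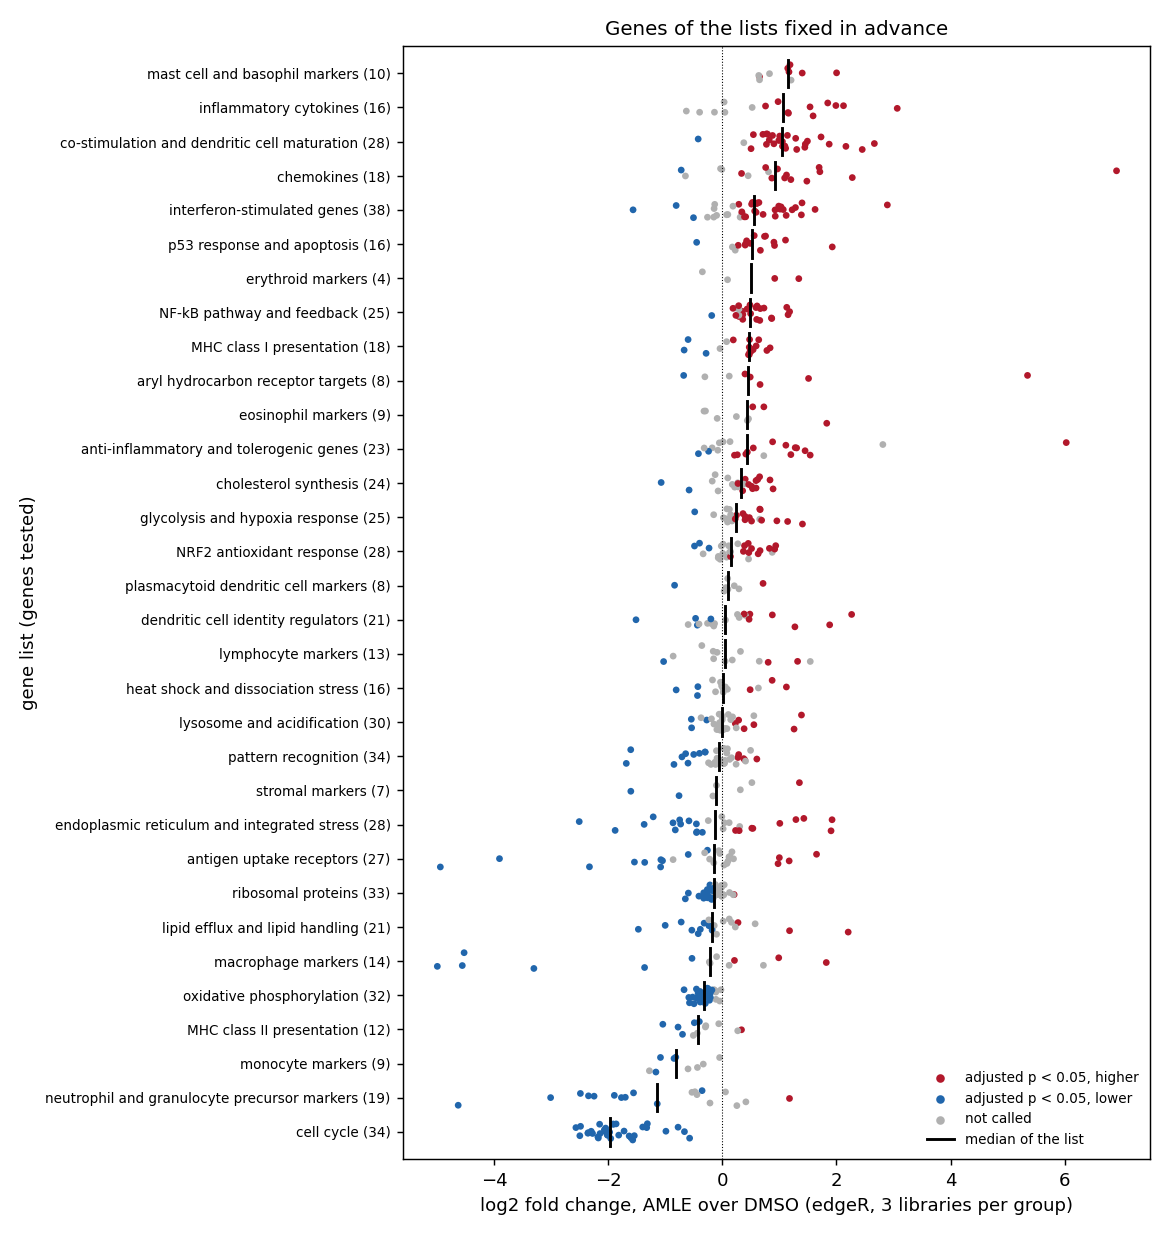
Log2 fold change of AMLE over DMSO for each tested member of the fixed lists, from edgeR with 3 libraries per group, with red for called higher, blue for called lower, grey for not called and a black bar at the list's median. All 34 cell cycle genes lie below 0, and 26 of 28 maturation genes are called higher.

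Markers of other cell types and of RNA quality moved beside these groups. Neutrophil and granulocyte precursor markers fell in 11 of 19 members and rose in 1 (13 and 1 adjusted over the list alone), with a median of −1.14 (camera adjusted p = 0.0017; adjusted p = 0.65 with an estimated correlation). The granule genes Elane (−4.62 ± 0.33), Mpo (−3.01 ± 0.21), Prtn3 (−2.48) and Ltf (−2.24) fell. S100a9, the most abundant member, was at 7746 ± 1919 CPM in DMSO and 5699 ± 1090 in AMLE (−0.44 ± 0.21, adjusted p = 0.13; 0.0027 with a replicate block and 0.026 without DMSO replicate 3). Cxcr2, a receptor of mature neutrophils, rose (1.18), a call lost without AMLE replicate 1 (0.052) or AMLE replicate 2 (0.053), and 2 members rose with a replicate block. Macrophage markers fell in 6 of 14 members and rose in 3 (6 and 3 adjusted over the list alone), with a median of −0.22 and a mean of −1.14 (camera adjusted p = 0.34). The complement genes C1qa (−4.99 ± 0.57), C1qc (−4.55 ± 0.46) and C1qb (−4.52 ± 0.52) and Fcrls (−3.30 ± 0.45) fell, and Cd63, the most abundant, was at 0.12 ± 0.07 (adjusted p = 0.20). Ms4a7 (1.82), Maf (0.99) and Adgre1 (0.21) rose. Maf was not called when any library other than AMLE replicate 3 was left out (0.063 to 0.11) and Adgre1 not without DMSO replicate 1, DMSO replicate 3, AMLE replicate 1 or AMLE replicate 2 (0.067 to 0.097), so that 1 rose in each of those 4 fits. Monocyte markers fell in 4 of 9 members and rose in 0 (4 and 0 adjusted over the list alone, and 0 higher at an unadjusted p under 0.05 and with DESeq2 or limma-voom), with a median of −0.81 (camera adjusted p = 0.025; adjusted p = 0.39 with an estimated correlation). They were Vcan (−1.16), Ly6c2 (−1.08), Ccr2 (−0.84) and Ms4a4c (−0.81). The last was not called without DMSO replicate 2, DMSO replicate 3, AMLE replicate 1 or AMLE replicate 3 (0.051 to 0.088), and 7 fell without both libraries numbered 3. Fn1 was at 862 ± 81.1 and 356 ± 258 CPM (−1.28 ± 0.47, adjusted p = 0.059), with 648 in AMLE replicate 3 against 262 and 159, and was called lower without AMLE replicate 3 (6.8e-04) and with limma-voom (0.030).

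Mast cell and basophil markers went up, with 6 of 10 members higher and 0 lower (7 and 0 adjusted over the list alone, with 0 lower at an unadjusted p under 0.05, with DESeq2 or with limma-voom, as for the eosinophil and erythroid lists) and a median of 1.16 (camera adjusted p = 0.014; adjusted p = 0.77 with an estimated correlation). Cpa3 (1.40) and Tpsb2 (2.00), both mast cell proteases, rose, as did Mcpt8, Fcer1a, Cyp11a1 and Hdc. The count was 3 without DMSO replicate 1, 2 without DMSO replicate 2, DMSO replicate 3, AMLE replicate 1 or AMLE replicate 2, 10 without AMLE replicate 3 and 10 with a replicate block. Prss34 was at 115 ± 39.2 and 181 ± 61.0 CPM (0.65 ± 0.34, adjusted p = 0.15; 1.4e-05 with a replicate block, 0.035 without AMLE replicate 3), with both libraries numbered 3 lowest in their group (69.8 and 110). Eosinophil markers rose in 3 of 9 members and fell in 0 (3 and 0 adjusted over the list alone; median 0.44, camera adjusted p = 0.18), namely Ccr3 (1.83), Il5ra (0.73) and Siglecf (0.53). Only 1 rose without DMSO replicate 1, 2 without DMSO replicate 2 or AMLE replicate 2 and 5 without AMLE replicate 3, and camera called the list without DMSO replicate 3 (0.041). Without both libraries numbered 3, 6 rose and camera called the list (0.0178). Prg2 was at 1168 ± 200 and 1608 ± 296 CPM (0.46 ± 0.17, adjusted p = 0.062; 0.013 with DESeq2 and 0.0093 without AMLE replicate 3).

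Lymphocyte markers rose in 2 of 13 members, Il7r (0.80 ± 0.10) and Lck (1.32), and 1, Nkg7 (−1.03), fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.63; 2 lower with a replicate block and without AMLE replicate 3). In the plasmacytoid list of 8, Tcf4 rose (0.72) and Ly6d fell (−0.83). The latter was not called when any library other than DMSO replicate 3 was left out (0.054 to 0.13), nor adjusted over the list alone (1 and 0; camera adjusted p = 0.35). Without AMLE replicate 3, 2 members rose. Bst2 was at 0.10 ± 0.06 (adjusted p = 0.19). Car2 (0.92 ± 0.09) and Epor (1.34) rose among 4 tested erythroid markers (2 and 0 adjusted over the list alone), too few for camera. Among 7 stromal markers Pecam1 rose (1.35 ± 0.35), and Lepr (−1.60) and Col1a1 (−0.76) fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.65). Pecam1 was not called without DMSO replicate 3, AMLE replicate 1 or AMLE replicate 2 (each 0.057) nor with no low-count filter (0.070). It was called with a replicate block (edgeR adjusted p = 0.0016). Col1a1 was not called when any library other than AMLE replicate 3 was left out (0.053 to 0.076).

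Ribosomal protein genes fell in 16 of 33 members and rose in 1, Rpl37 at 0.21 (16 and 1 adjusted over the list alone), by a median of −0.15 (camera adjusted p = 0.013; adjusted p = 0.77 with an estimated correlation). Only 9 fell without DMSO replicate 2, 3 rose without AMLE replicate 3 and 2 with a replicate block. Camera did not call the list without AMLE replicate 3 (0.11) or without both libraries numbered 3 (0.14). Rpl37 was not called when any library other than AMLE replicate 3 was left out (0.054 to 0.087). Rplp0, the most abundant member, was at 0.01 ± 0.06. In the p53 and apoptosis list 13 of 16 members rose and Bid (−0.45) fell (14 and 1 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 4.1e-05; adjusted p = 0.39 with an estimated correlation). Cdkn1a, which arrests the cell cycle, rose 1.89-fold (0.92 ± 0.10), and Mdm2 (0.91) and Gdf15 (1.93) rose. Heat shock and dissociation genes were split, with Egr1 (1.12), Junb (0.87) and Jun (0.49) higher and Hspd1 (−0.81), Hspa8 (−0.43 ± 0.06) and Hsp90aa1 (−0.43) lower among 16 (3 and 3 adjusted over the list alone; camera adjusted p = 0.81). Hsp90aa1 was not called without DMSO replicate 1, DMSO replicate 2 or AMLE replicate 1 (0.071 to 0.089). Rn45s, a ribosomal RNA precursor, took 0.40% of the counts of AMLE replicate 2 and 0.062 to 0.084% of those of the other libraries.

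Outside the lists, the largest rises under the naming rule were Tcaf2 (4.06 ± 0.47), Apol7c (3.46 ± 0.22) and Lad1 (3.06 ± 0.36), next to Ccl24, Arg1 and Cd200 above. Apol7c stood at 62.2 ± 15.3 CPM in DMSO and 683 ± 135 in AMLE, and belongs to a family with close copies, so its count is uncertain.

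Open chromatin was compared by the presence of called peaks. AMLE libraries had 15805 and 15597 peaks and DMSO libraries 18460 and 19225, so that the AMLE mean of 15701 ± 147 (SD, n = 2) lay 16.7% below the DMSO mean of 18843 ± 541. The exact permutation test gave p = 0.333, the smallest that 2 against 2 allows. Peaks covered 10.4 and 10.3 Mb in DMSO and 8.86 and 9.16 Mb in AMLE. Of 24542 merged regions, 12033 had a peak in all 4 libraries, 1460 in both DMSO libraries only and 113 in both AMLE libraries only, whereas the 4 mixed pairs of libraries alone shared 283 to 377. With the same number of peaks (15597) in each library, 731 regions were DMSO-only and 381 AMLE-only against 277 to 359 for mixed pairs. The peak lists give no read totals, so depth is unknown and absence of a peak is not absence of open chromatin. Without DMSO replicate 1, DMSO replicate 2, AMLE replicate 1 and AMLE replicate 2, AMLE-only regions numbered 305, 475, 1193 and 1524, and DMSO-only regions 3969, 3528, 2402 and 2499, a single library then standing for its group.

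**Figure D3:**
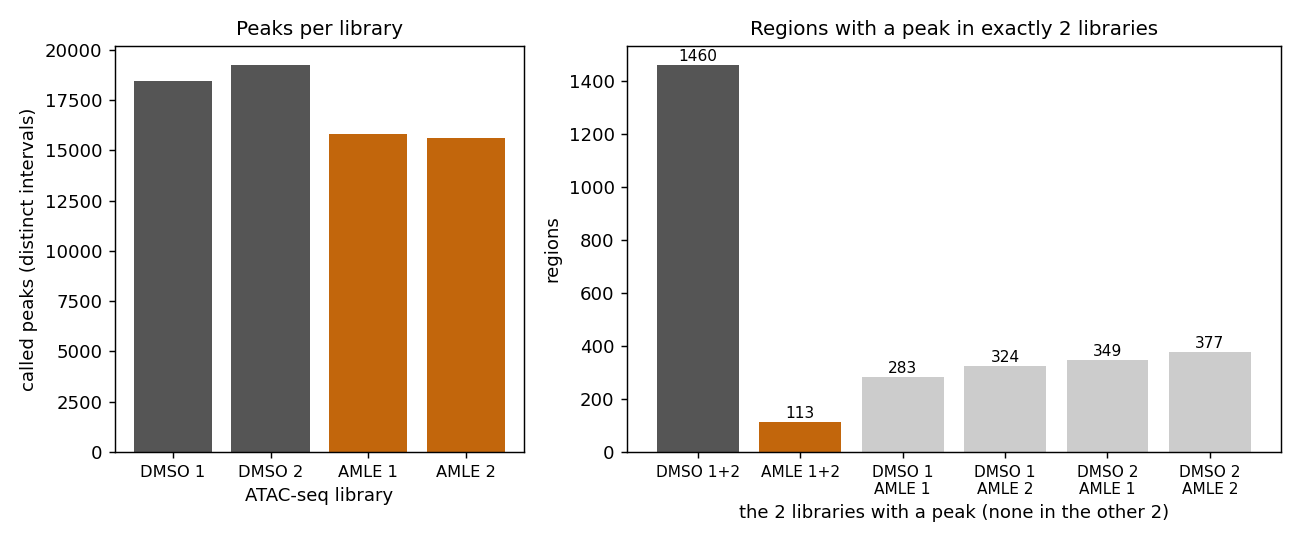
Left, called peaks (distinct intervals) in each of the 4 ATAC libraries. Right, number of merged regions with a peak in exactly 2 libraries, for the DMSO pair (1460), the AMLE pair (113) and the 4 mixed pairs in light grey (283 to 377), both axes starting at 0.

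The AMLE-only region with the highest rank lay on chromosome 13, 49213700 to 49214184 (mm10), in or within 1 kb of 1110007C09Rik, with −log10 q of 13.4 and 19.5 in the AMLE libraries. The next were at chromosome 19, 12794744 to 12795126, at Lpxn and Zfp91, and chromosome 6, 149307797 to 149308400, away from tested genes. The leading DMSO-only regions were at chromosome 11, 104424884 to 104425515, at Kansl1 (−log10 q 32.5 and 46.9), chromosome 2, 59160517 to 59160821, at Pkp4, and chromosome 4, 117125819 to 117126330, at Btbd19 and Tctex1d4. Exons, introns and strand were not used here. Among regions present in all 4 libraries 59.6% lay within 1 kb of a tested gene's end, against 24.8% of AMLE-only and 14.7% of DMSO-only regions.

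Among the named genes, including members of lists for which peaks were not planned to be looked up, Cd40, Tnf, Hmox1 and Cyp1b1 had a gene-end region with a peak in all 4 libraries, and Ccr7 had at least 2 in each. Cd86 had 3 and 4 regions with a peak in or near its span in the DMSO libraries and 1 and 2 in the AMLE libraries, with a gene-end peak in all but AMLE replicate 2. Cd80 had 2 such regions in DMSO replicate 2, 1 of them at a gene end, and 1 in AMLE replicate 2. H2-Ab1 had 1 region in each DMSO library, not the same one, and 0 in AMLE, and Il6 had 1 in DMSO replicate 1 alone. Cd200 had 1 region in each library but AMLE replicate 2, which had 2. C1qb lacked a peak in AMLE replicate 1 alone, C1qc in AMLE replicate 2 alone, and Fcrls had one in AMLE replicate 1 alone. Il12b, Arg1, Ccl24, Tcaf2, Lad1, C1qa, Elane and Mpo had no peak in or near their span. Apol7c had a gene-end peak in each AMLE library and none in DMSO, but at different regions, so neither counted as AMLE-only. Fn1 held a DMSO-only region at a gene end and Flt3 one within its span. In the antigen uptake list 6 of 27 placed genes held a DMSO-only region in or near their span, among them Cd36, Ly75 and Clec10a, and 0 an AMLE-only region. Of all 13032 placed genes, 813 held a DMSO-only and 76 an AMLE-only region. Genes holding DMSO-only regions were longer than other genes with regions (median span 55.9 kb against 22.2 kb). The dendritic cell identity list held DMSO-only regions at Spi1, Zbtb46, Flt3 and Batf3 and an AMLE-only region at Id2; these genes were chosen after their values were seen and the lists were not tested for enrichment.

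Gene expression was set beside region class. Of 31 genes with an AMLE-only region at a gene end, 7 were higher and 8 lower in AMLE RNA, and of 230 with a DMSO-only region 64 were higher and 61 lower, against 2046 and 2730 of 9549 others with regions. A contrast outside the plan set DMSO-only against other genes, with p-values unadjusted over its settings. Its odds ratio was 1.40 (Fisher's exact test, two-sided, p = 0.0673). It was 1.63 without DMSO replicate 1 (Fisher's exact p = 0.000115), 1.46 without DMSO replicate 2 (Fisher's exact p = 0.00815), 1.35 without AMLE replicate 1 (Fisher's exact p = 0.0233) and 1.32 with the deposited consensus lists (Fisher's exact p = 0.0113). It was 1.28 without AMLE replicate 2 (Fisher's exact p = 0.0598), 1.20 with reciprocal overlap (Fisher's exact p = 0.244), 1.13 with the 3 kb window (Fisher's exact p = 0.422) and 1.10 for peaks with −log10 q of at least 5 (Fisher's exact p = 0.570). With the same number of peaks in each library it was 0.943 (Fisher's exact p = 0.907), and over the gene span 2.02 (Fisher's exact p = 6.7e-12). Over the span, genes with regions of mixed pairs also had odds ratios of 1.77 to 2.27, so the excess was not particular to DMSO-only regions. The odds ratio of higher to lower between AMLE-only and DMSO-only genes was 0.834 (Fisher's exact test, two-sided, p = 0.79), which does not show that the classes are alike. Direction depended on the setting: the log2 odds ratio was −0.25 here, 1.46 for peaks with −log10 q of at least 5 (Fisher's exact p = 0.19) and 1.33 with the same number of peaks in each library (Fisher's exact p = 0.0075, unadjusted over 10 alternatives). It was 0.76 without AMLE replicate 1, 0.72 without AMLE replicate 2, 0.36 without DMSO replicate 2 and −0.37 without DMSO replicate 1. In each of these a single library stood for its group. With reciprocal overlap it was −0.59 (Fisher's exact p = 0.353). Each log2 odds ratio was computed with a small constant added to every count, so it is not the log2 of the plain odds ratio. Fisher's tests used the plain counts.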

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

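The alternatives without both libraries numbered 3, without the Rn45s count and with a window over the gene span were chosen after seeing the data; the other tests here were planned. Under the alternatives run, 0 of 67 named genes reversed direction and 56 kept their side of the threshold. The 11 others were H2-Ab1, Tnf, Ccl24, Arg1, Havcr2, Ctsk, S100a9, Fn1, Prss34, Prg2 and Pecam1. All 67 kept their side with RLE factors, library size only or a mean CPM of at least 1; 2 gained a call with DESeq2, 2 lost and 1 gained a call with limma-voom, and 4 lost a call with no low-count filter. Genes called higher and lower numbered 3138 and 3201 with RLE factors, 2965 and 3182 with DESeq2, and 3001 and 3390 with limma-voom. No gene called in the main design was called in the opposite direction by any RNA alternative, and the median gene shifted by at most 0.0146 on the log2 scale. Tested against a 1.5-fold change, 532 genes were higher, 575 lower and 423 at least 2-fold higher, fewer by construction since the test asks for a larger change. Leaving out 1 library gave 2263 to 3308 genes higher and 2666 to 3475 lower, 573 to 943 at least 2-fold higher and 526 to 636 at least 2-fold lower, and 10 to 14 lists higher and 5 to 6 lower. Without both libraries numbered 3, 3436 genes were higher and 3612 lower, with 13 lists higher and 5 lower, and without the Rn45s count 3005 and 3347 genes.

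With the replicate number as a block, 3434 genes were higher and 3813 lower, 750 and 593 of them at least 2-fold. The replicate block ended the call on Havcr2 (adjusted p = 0.067) and brought S100a9 (0.0027) and Prss34 (1.4e-05) past the threshold. Among lists it called MHC class II lower (0.023) and no longer called NRF2 (0.055), so that camera called 11 higher and 6 lower. It changed no other call among named genes and lists tested by camera. With fry, 12 lists were higher and 5 lower, and with the replicate block 13 and 8, and the cause was not tested. Camera with an estimated correlation called 0 lists higher and 0 lower, and the cause was not tested.

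AMLE-only regions numbered 44 among peaks with −log10 q of at least 5, 381 with an equal number of peaks, 270 with reciprocal overlap and 747 with the deposited consensus lists, against 113; leaving out 1 library gave 305 to 1524. DMSO-only regions numbered 731 with an equal number of peaks and 3545 with the consensus lists, against 1460, and 2402 to 3969 when 1 library was left out. Leaving out a library raises these counts by construction. Either 1 peak is then asked for in place of 2, or 1 library fewer can exclude a region. The consensus lists, being intersections of replicates, also raise them by construction, since a peak in only 1 library of the other group no longer excludes a region. An equal number of peaks drops weak peaks almost only from the DMSO libraries, which by construction lowers DMSO-only and raises AMLE-only regions. For the other settings the cause was not tested. The ratio of AMLE to DMSO peaks was 0.833, or 0.775 for peaks with −log10 q of at least 5 (the cause was not tested), and 0.817 to 0.851 when 1 library was left out. An equal number of peaks, reciprocal overlap, the consensus lists and the gene windows give no value for that ratio. The log2 odds ratio between region class and expression (−0.25) changed sign with −log10 q of at least 5 (1.46), an equal number of peaks (1.33), the 3 kb window (0.43), the gene span (0.18) and the consensus lists (0.46). It was −0.59 with reciprocal overlap and ran from −0.37 to 0.76 when 1 library was left out, and the cause was not tested. Only 31 genes entered its AMLE-only class. Read totals of the ATAC libraries were not analysed here, so their depth limits these counts to an unknown extent.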

Other observations

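The tests of the share of the main cell type, of dividing precursors, of the number of peaks and of ATAC depth, and the counts of genes over other splits of the libraries, were chosen only after the result was seen.

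Several genes outside the fixed lists changed in AMLE, and they were picked after their values were seen. Slc7a2, a transporter of arginine, rose from 83.5 to 364 CPM (log2 fold change 2.12 ± 0.10, SE, n = 3 per group). Prdm1, which encodes the transcriptional repressor Blimp-1, rose by 1.97 ± 0.16 and Zfp366, the zinc finger protein DC-SCRIPT, by 1.61 ± 0.13. Aldh1a2, an enzyme that makes retinoic acid, rose from 74.8 to 233 CPM (1.64 ± 0.28), and Lrrc32, which encodes the latent TGF-beta anchor GARP, rose by 1.97 ± 0.21. Jag1, a Notch ligand (1.53 ± 0.14), Mir155hg, the host transcript of a microRNA of activated immune cells (2.03 ± 0.26), Ltc4s, the leukotriene C4 synthase (1.71 ± 0.15), and the cell cycle inhibitor Cdkn2b (1.64 ± 0.18) rose as well.

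Among genes that fell, Asgr2, a lectin subunit, went from 104 to 13.2 CPM (−2.97 ± 0.34), Slamf9 fell (−2.82 ± 0.34), and Ms4a3, a gene of granulocyte and monocyte progenitors, went from 86.1 to 17.1 CPM (−2.33 ± 0.25). Ccnd1, a cyclin of the G1 phase, fell (−2.13 ± 0.18). Slamf1 rose (2.50 ± 0.46). Tcaf1 fell (−0.60 ± 0.13) while its relative Tcaf2 rose (4.06 ± 0.47).

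Markers of other cell types moved in AMLE, granulocyte precursor, monocyte and several macrophage markers down and mast cell and basophil markers up, beside the fall of all 34 cell cycle genes. A change in the share of the main cell type alone would move them alike. The medians of the mast cell and basophil list and the neutrophil list were 2.30 apart on the log2 scale, more than the larger SD of their members (1.40). These lists were compared after 1 was seen to rise and the other to fall, so the outcome was known. The rising list also depended on the fit. Without a block, fry gave adjusted p = 0.106, and as few as 2 of 10 members were called when 1 library was left out. With a replicate block 10 were called (camera adjusted p = 8.5e-05, fry adjusted p = 0.0168), as they were without AMLE replicate 3. The comparison cannot decide whether such a change is the whole cause. Fewer dividing precursors may add to the falls, with the cell cycle list at a median of −1.96, but bulk libraries hold no cell counts, so this cannot be told apart from a lower level per cell. An effect of the extract on the expression of these genes stays open and was not tested apart from a change in cell make-up. S100a9, the most abundant granulocyte marker, was at 7746 CPM in DMSO and 5699 in AMLE, and was called lower with a replicate block, without DMSO replicate 3 and without both libraries numbered 3, but not in the main design.

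AMLE libraries had fewer peaks, and 1460 regions were DMSO-only against 113 AMLE-only. The number of peaks called is not the whole cause, since with the same number in each library DMSO-only regions were still 2.04 times the highest mixed pair. In that setting, however, AMLE-only regions numbered 381, above the highest mixed pair (359), and the ratio of DMSO-only to AMLE-only regions went from 12.9 to 1.92. Its weakest peaks were dropped almost only from the DMSO libraries, which by construction lowers DMSO-only and raises AMLE-only regions. The change in the ratio therefore cannot say how much of the imbalance the number of peaks explains. Lower depth or signal over background in the AMLE libraries could give the same pattern: of regions with −log10 q of at least 15 in both DMSO libraries 0.939% (95% Clopper-Pearson interval 0.745 to 1.17, counting error only) had no peak in either AMLE library, against 0 of 6429 (upper bound 0.0574%) the other way and at most 0.14% for mixed pairs. Strong regions were thus lost in 1 direction, as lower signal gives, but the peak lists hold no read totals, so it cannot be told apart from a loss of accessibility, which also stays open and untested.

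Genes with a DMSO-only region in or within 1 kb of their span were called higher in AMLE more often than other genes with a call, with 262 higher and 163 lower (61.6% against 44.1%; odds ratio 2.04, Fisher's exact p = 3.8e-12, genes not being independent). That odds ratio had been seen before its tests were set. The hypothesis that this is particular to DMSO-only regions found no support, since genes with regions of mixed pairs had odds ratios of 1.77 to 2.27 and those of the AMLE pair 2.52, which is consistent with a property of genes that hold regions found in few libraries. Gene length is a candidate (median span 55.9 kb against 22.2 kb), and within 10 bins of span the odds ratio was lower, at 1.55. Its 95% interval of 1.26 to 1.92 takes genes as independent. This argues against differences in length between bins as the whole cause, but span still varies within a bin. Within the same bins mixed pairs were at 1.35 to 1.83. No biological explanation was tested.

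With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. All splits but the real one have both groups on each side in unequal numbers. Part of the treatment difference thus stays between their sides, and part adds to the spread within them. Their counts of genes and lists are therefore no reference without treatment. The real split gave 6350 genes and 1297 at least 2-fold, and the highest of the others 0 and 0 by edgeR (up to 447 at an unadjusted p under 0.05), so 1 of 10 splits reached each count. For lists called by camera, 2 of 10 splits reached the real count of 17; the other was that of DMSO replicates 1 and 3 with AMLE replicate 3 against the rest, with 18, which keeps both libraries numbered 3 together. With a replicate block camera called 11 lists higher and 6 lower in the real split. The 3 other splits that part all 3 numbered pairs, as the real one does, gave 8 to 15 lists.

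Retnla was at 16.5, 29.0 and 1.07 CPM in AMLE replicates 1, 2 and 3 (log2 fold change 2.81, edgeR adjusted p = 0.0575), lowest in the same library as Arg1 and Ccl24. Mcpt8 was lowest in the library numbered 3 of both groups, at 34.6 CPM in DMSO against 66.5 and 71.4, and 74.1 in AMLE against 154 and 160.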
